A study of Rattus norvegicus with 12 samples.

How the data were processed

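Small RNA was sequenced from exosomes of rat serum in 12 libraries, 3 in each of 4 groups. Per the labels' protocols, male Sprague-Dawley rats of 9 weeks received a single oral dose of a compound toxic to the testis or of its vehicle, and blood was taken 24 h later. Ethylene glycol monomethyl ether (EGME), a glycol ether solvent, was given at 2000 mg/kg in water (10 mL/kg). The compound the labels call CBZ was given at 400 mg/kg in corn oil (5 mL/kg). The control groups, called water and oil here, received the vehicle. Per the labels, serum was cleared for 20 min at 16500 g, and vesicles were pelleted from 2.7 mL of it in 70 min runs at 208000 g, which also pellets protein particles that carry RNA. Libraries were made with the NEBNext Multiplex Small RNA set and sequenced on a MiSeq. Libraries were assigned to groups and replicate numbers by their titles. The titles number the libraries within each group but do not say that each came from a separate rat, so the p-values measure the spread between these libraries, part of which may be technical.

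The authors deposited 1 table of raw counts for the water and EGME libraries and 1 for the oil and CBZ libraries. Each holds whole-number counts of reads per feature, and lists only features with at least 1 read in some library, 3280 features in the first and 1709 in the second. The features are mature miRNAs, piRNAs, tRNA genes named by chromosome and anticodon, and Ensembl transcripts typed as rRNA, misc_RNA, snoRNA and other classes. The authors also deposited, per comparison, a table of normalized signal, which the files call normalized read counts. Within each library these values are the raw counts times 1 constant, and the tables hold only miRNAs, piRNAs and tRNAs with more than 10 counts in all (442 and 366 features). Per the submitters' processing notes edgeR was used, with no version stated. The aligner, the genome build and the rule for reads that match several gene copies are not given in the sources used here. No coordinates are therefore printed. The Ensembl transcripts were left without gene names, since 0 of their IDs matched the gene table used here.

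The depth was low and unequal. The total of assigned counts was 893864, 970329 and 858906 in the water libraries, 608892, 1235814 and 867968 in the EGME libraries, 392677, 196460 and 598200 in the oil libraries, and 443084, 410819 and 405976 in the CBZ libraries. A count of 0 allows a level of up to 3 counts, which is 2.43 to 15.3 CPM (counts scaled to a common library total) depending on the library. Intervals on the share of a single library are exact 95% binomial (Clopper-Pearson) intervals. The libraries carry no molecular identifiers, so intervals and floors cover counting error only. The lowest chi-square per degree of freedom between 2 libraries of 1 group was 21.6, above counting noise, so no library was treated as a second deposit of another. This does not exclude repeat preparations from 1 serum.

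Raw counts were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3, robust fit, TMM scaling, filterByExpr with a minimum count of 10), separately for each toxicant against its vehicle, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. All tests were two-sided unless stated. Standard errors (SE) were taken from the fold change and its F statistic. Values per library are TMM-scaled CPM. The filter left 330 features for EGME and 244 for CBZ. The contrast of EGME against water minus CBZ against oil was fitted over all 12 libraries on the 1334 features named in both raw tables, 327 of which were tested. The tables list no feature without a read, so a feature named in 1 table alone was left out of that contrast. Shares of counts per RNA class were compared by an exact permutation test, for which 3 libraries against 3 cannot give a p below 0.1. The 27 fixed lists were tested with camera in limma 3.58.1 (preset correlation 0.01, lists with at least 3 tested members), with an estimated correlation and with fry beside it.

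The design, the lists, the tests and most alternatives were chosen before the data were examined. The alternatives were DESeq2 1.42.0 size factors, upper quartile or no scaling, no filter, a filter of 10 counts in 3 libraries, the DESeq2 Wald test, limma on log2 of the authors' normalized values plus 1, all 12 libraries in 1 fit, miRNAs alone, the replicate number as a block, and leaving out each library. Added after seeing the data were near-identical gene copies counted once (copies whose counts differ by at most 5 percent or 3 counts in every library, with a mean of at least 20 counts), the authors' feature set with the quasi-likelihood and the exact test of edgeR, lists among miRNAs alone, correlations within a class, and every alternative applied to miRNAs alone. In the fit of miRNAs alone both the scaling and the spread come from mature miRNAs only. It was 1 of the alternatives, and describing it at length was decided after its values were seen.

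The rule for named small RNAs took, per comparison, up to 12 of the largest rises and 12 of the largest falls past the threshold with every treated library on one side of every control; where fewer than 10 passed, those of smallest p up to 10; the 5 of highest mean CPM; and for each list its 3 members of highest mean CPM. Where copies share nearly all counts 1 is named. For lists without a call, members are named sparingly. Applying the first part of the rule to the fit of miRNAs alone was also decided after the values were seen, and the miRNAs with overlapping libraries there are named as such. For the contrast of the toxicants the 6 smallest p were taken.

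The tests were checked on simulated counts drawn from the means, library sizes and dispersions of the real libraries, in 5 data sets with 40 changed features each. Among all classes, edgeR called 20% of 2-fold changes and 86.2% of 4-fold changes for EGME (330 features), but 4.62% and 44.6% for CBZ (244 features). For miRNAs alone it called 58.5% and 98.5% for EGME (141 miRNAs), and 53.8% and 92.3% for CBZ (115 miRNAs). Of the edgeR calls in all classes 6.33% were false for EGME and 5.88% for CBZ; for the DESeq2 Wald test these shares were 3.95% and 20%. Among miRNAs alone 5.47% and 3.48% of the edgeR calls were false. A list made 2-fold higher was called in 5 of 5 simulations for either comparison, with 2 false calls in 69 tests of other lists for EGME and 0 in 59 for CBZ. Members of the simulated lists varied independently of each other. In the real EGME comparison the estimated correlation was 0.56 within the tRNA list and 0.72 within the rRNA list. These counts of false calls therefore do not carry over to camera calls of correlated lists. Figures were drawn with matplotlib 3.10.9.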

Results

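The series asks which small RNAs in serum exosomes mark injury of the testis. Small RNA counts were compared for 2 toxicants, each against its own vehicle, with 3 libraries per group (water, EGME, oil and CBZ). Assigned counts ranged from 608892 to 1235814 per library in the water and EGME groups and from 196460 to 598200 in the oil and CBZ groups, and 839 to 1579 features had at least 1 read in a library. The most abundant feature in every group mean was a single misc_RNA transcript, ENSRNOT00000090410.1, which ranged from 24.8% (interval 24.7 to 24.9) of the counts in water library 3 to 51.4% (51.3 to 51.6) in EGME library 1. In the other comparison it ranged from 12.0% (11.8 to 12.1) in oil library 2, where miR-148a-3p was above it, to 27.4% (27.3 to 27.5) in oil library 3. Among mature miRNAs miR-148a-3p and let-7i-5p were the most abundant in the water and EGME libraries, and miR-148a-3p in the oil and CBZ libraries.

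The first comparison asks which small RNAs differ in serum exosomes 24 h after EGME. Among mature miRNAs tested alone, 8 of 141 rose and 5 fell. The rises included miR-10a-5p, encoded within a HOX gene cluster, by 1.30 on the log2 scale (SE 0.269, edgeR adjusted p = 0.000302), from 1730 ± 728 to 4252 ± 426 CPM of the miRNA counts (SD, n = 3 libraries per group). They also included miR-423-5p by 1.32 (SE 0.273, adjusted p = 0.000302) and miR-128-3p, a miRNA enriched in brain, by 1.47 (SE 0.337, adjusted p = 0.00850). The miRNA miR-215, a relative of miR-192 that responds to p53, fell by 1.26 (SE 0.264, adjusted p = 0.000302), from 12206 ± 2027 to 5085 ± 1298 CPM. The cartilage-enriched miR-140-3p fell by 0.99 (SE 0.246, adjusted p = 0.00381), and miR-150-5p, abundant in lymphocytes, fell by 0.86 (adjusted p = 0.0229).

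Smaller rises were those of let-7d-3p (0.85, adjusted p = 0.0229), miR-22-3p (0.82, adjusted p = 0.0264) and miR-3559-3p (0.90, adjusted p = 0.0264). In miR-320-3p (0.93, adjusted p = 0.0229) and let-7b-5p (0.83, adjusted p = 0.0311) the libraries of the groups overlapped. In the other 11 called miRNAs every EGME library lay on one side of every water library. Chance gives this for 10% of unselected miRNAs, but these were selected by small p in the same libraries. The separation is therefore no support beside that p. With the scaling of all classes the libraries overlapped in miR-128-3p. Falls were also called for miR-93-5p, of the miR-106b-25 cluster (-0.89, adjusted p = 0.0214), and for the scarce miR-455-3p (-1.79, adjusted p = 0.0229). All 13 kept their sign under every alternative that tested them. The count was 6 with DESeq2 size factors (4 higher, 2 lower), 8 without scaling (3 higher, 5 lower), 14 with the DESeq2 Wald test (10 higher, 4 lower) and 1 with limma on the authors' normalized values. It was 3 without EGME library 1, 6 without EGME library 3 and 7 without water library 2.

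Over all RNA classes edgeR called 0 of 330 features for EGME, with 59 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0906, and the DESeq2 Wald test called 20 (7 higher, 13 lower). The smallest p belonged to miR-10a-5p (1.56, SE 0.363, edgeR adjusted p = 0.0906). Next came fragments of tRNA genes, which were lower: the LeuTAG gene by a log2 difference of -2.12 (SE 0.500), a ValCAC gene by -1.83 (SE 0.433) and a ValAAC gene by -1.71 (SE 0.410), each at adjusted p = 0.0906. Also lower, at the same adjusted p, was the mitochondrial rRNA ENSRNOT00000069133.1 (-1.51, SE 0.368, from 171 ± 66.2 to 59.8 ± 11.3 CPM), and piR-64201 was lower by -1.45 (adjusted p = 0.0948). The remaining 4 of the 10 smallest p were near-identical valine tRNA genes, with values from -1.61 to -1.60 that rest on nearly the same reads. Of the abundant features, the misc_RNA ENSRNOT00000090410.1 was higher by 0.71 (adjusted p = 0.442), a GlyGCC tRNA gene lower by -0.63 (adjusted p = 0.557), and miR-148a-3p (0.25) and let-7i-5p (0.12) close to the vehicle, none past the threshold. With upper quartile scaling, which moved the median of all features from -0.02 to 0.31, edgeR called 34 (23 higher, 11 lower), and without scaling 27 (3 higher, 24 lower). The count was 60 without EGME library 2, which had the lowest TMM factor (0.683), and 1 without water library 3.

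The fixed lists gave 5 calls of 15 for EGME by camera. The tRNA fragments were lower (67 of 74 tested genes, median log2 difference -0.85, camera adjusted p = 3.17e-17; adjusted p = 0.774 with an estimated correlation), with a median of -0.38 without water library 3 and -1.29 without EGME library 2. Adjusted over the list alone 11 of them fell, against 0 over all features. Many of these tRNA genes are near-identical copies that rest on nearly the same reads, with sets of 10 histidine, 8 glycine and 8 valine genes. The counts of genes and the camera p therefore count the same reads repeatedly. The kidney and epithelial miRNAs were higher (5 of 5, median 0.97, camera adjusted p = 0.00403; adjusted p = 0.774 with an estimated correlation), with miR-10a-5p, the only member that rose adjusted over the list alone, miR-182 (0.97, edgeR adjusted p = 0.230) and miR-203a-3p (0.74, adjusted p = 0.456). The let-7 family, which restrains proliferation, was higher in 8 of 10 members (median 0.70, camera adjusted p = 0.0106; adjusted p = 0.774 with an estimated correlation), though its most abundant members let-7i-5p (0.12), let-7f-5p (0.08) and let-7g-5p (-0.07, but 0.23 with upper quartile scaling) were near 0. The platelet miRNAs were higher in 9 of 9 members (median 0.43, camera adjusted p = 0.0167; adjusted p = 0.774 with an estimated correlation), among them miR-21-5p (0.12), miR-191a-5p (0.49) and miR-24-3p (0.41). The let-7 and platelet calls were lost without water library 3 (adjusted p = 0.0686 each) and without EGME library 3 (0.0663 and 0.0829). The rRNA fragments were higher in 29 of 29 (median 0.30, camera adjusted p = 0.00329; adjusted p = 0.797 with an estimated correlation). That call was lost without water library 1 (adjusted p = 0.327), without EGME library 2 (0.425, median -0.09) and with near-identical copies counted once. Adjusted over the list alone 0 members of the let-7, platelet and rRNA lists passed with edgeR. Fry called 0 of 15 lists, and among miRNAs alone camera called 0 of 11.

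The other lists tested for EGME did not pass. Red blood cell miRNAs had 6 of 10 members lower (camera adjusted p = 0.803), with a median of -0.08, a mean of 0.01 and a test pointing up. Within the list miR-486 was higher (0.76, edgeR adjusted p = 0.309) and miR-451-5p lower (-0.17, adjusted p = 0.846), both abundant in erythrocytes. Liver miRNAs (camera adjusted p = 0.803) also had a median of -0.21 against a mean of 0.02, and the liver-specific miR-122-5p was higher by 0.93 (edgeR adjusted p = 0.349). White blood cell miRNAs (camera adjusted p = 0.700), p53-responsive miRNAs (0.573), vascular and fibroblast miRNAs (0.573), the miR-17-92 and related clusters (0.573), the miR-30 family (0.663), muscle miRNAs (0.516), piRNAs (0.803) and snoRNA and snRNA fragments (0.516) gave no call. Adjusted over the list alone 1 muscle miRNA rose (miR-206-3p, 1.25), 1 p53-responsive miRNA fell (miR-215) and 1 piRNA fell (piR-64201).

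**Figure D1:**
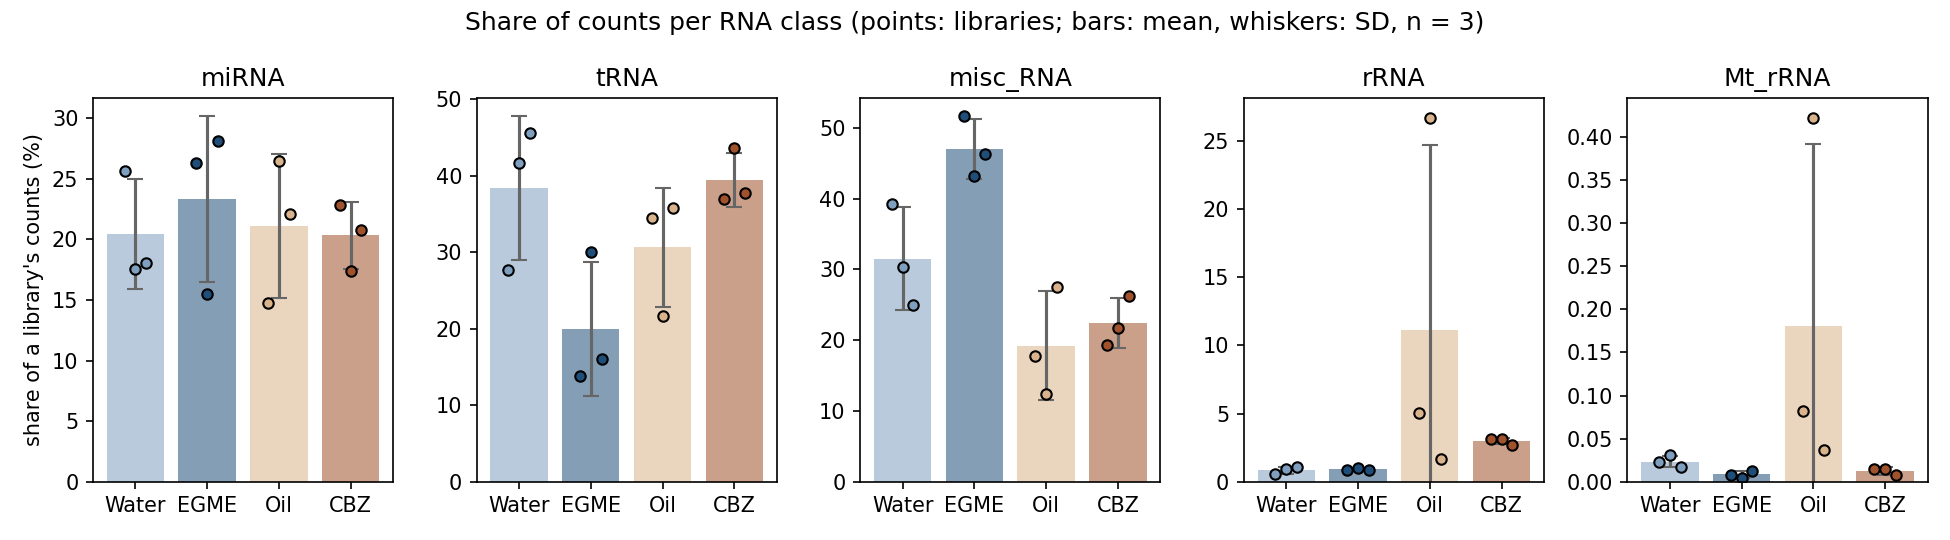
Share of each library's counts (%, vertical axes starting at 0, a separate scale per panel) assigned to miRNA, tRNA, misc_RNA, rRNA and mitochondrial rRNA in the water, EGME, oil and CBZ groups. Points are libraries, bars are means and whiskers are SD (n = 3, drawn only above 0). Counts are as deposited, so near-identical gene copies are each counted. The mean tRNA share was 38.3% with water and 20.0% with EGME (8.43% and 3.53% with copies counted once), and 1 oil library held 26.7% rRNA.

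By share of counts as deposited, tRNA fragments made up 38.3% ± 9.41 of the water libraries and 20.0% ± 8.78 of the EGME libraries (SD, n = 3, exact permutation p = 0.2). Near-identical gene copies each enter this share. With such copies counted once it was 8.43% with water and 3.53% with EGME (exact permutation p = 0.2). The misc_RNA share as deposited was 31.5% ± 7.26 with water and 47.0% ± 4.29 with EGME. Every EGME library was above every water library (exact permutation p = 0.1, the smallest that 3 against 3 allow). With copies counted once the misc_RNA share was 47.1% with water and 57.4% with EGME. Mitochondrial rRNA was lower in every EGME library, at 0.0236% ± 0.00671 against 0.00859% ± 0.00360 (exact p = 0.1), and so was mitochondrial tRNA, at 0.00884% ± 0.00202 against 0.00472% ± 0.00149 (exact p = 0.1). The shares of miRNA (20.4% and 23.3%, exact p = 0.7), piRNA (8.37% and 8.43%, exact p = 1) and rRNA (0.863% and 0.934%, exact p = 0.9) differed by less than the spread between libraries. Over 12 classes the lowest Benjamini-Hochberg adjusted value was 0.3.

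The second comparison asks the same of CBZ against oil. Among mature miRNAs tested alone, 9 of 115 rose and 4 fell. The rise of miR-423-5p was 1.54 on the log2 scale (SE 0.261, edgeR adjusted p = 3.38e-05), from 898 ± 283 to 2679 ± 166 CPM of the miRNA counts (SD, n = 3 libraries per group), and that of the brain-enriched miR-128-3p was 1.15 (SE 0.280, adjusted p = 0.00397). The myeloid miRNA miR-223-3p fell by 1.18 (SE 0.257, adjusted p = 0.00168), from 2746 ± 773 to 1211 ± 234 CPM. The erythrocyte miRNA miR-451-5p fell by 0.92 (SE 0.229, adjusted p = 0.00397), miR-93-5p by 1.13 (SE 0.272, adjusted p = 0.00397) and miR-185-5p by 1.03 (adjusted p = 0.00397).

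Further rises were called for miR-320-3p (0.97, edgeR adjusted p = 0.0214), miR-27a-5p (0.96, adjusted p = 0.0214), miR-10a-5p (0.85, adjusted p = 0.0214), miR-143-3p, abundant in smooth muscle (0.78, adjusted p = 0.0214), and let-7d-5p (0.77, adjusted p = 0.0214). The endothelial miR-126a-3p (0.71, adjusted p = 0.0360) and miR-24-3p (0.70, adjusted p = 0.0299) also rose. In all 13, selected by small p in the same libraries, every CBZ library lay on one side of every oil library. All 13 kept their sign under every alternative that tested them. The split of the calls depended on the scaling and the filter. It was 1 higher and 13 lower with upper quartile scaling, which moved the median over miRNAs from 0.03 to -0.35, and 7 higher and 5 lower with DESeq2 size factors. Without scaling, where the median was 0.24, it was 3 higher and 0 lower, and without a filter 3 higher and 11 lower. The DESeq2 Wald test called 19 (10 higher, 9 lower) and limma on the authors' normalized values 1. Without CBZ library 1 edgeR called 0 of 113 miRNAs, with 23 at an unadjusted p under 0.05. Without CBZ library 2 it called 0 of 121, with 18 at an unadjusted p under 0.05, and without CBZ library 3 it called 7.

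Over all RNA classes edgeR called 0 of 244 features for CBZ, with 64 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0773, and the DESeq2 Wald test called 24 (5 higher, 19 lower). The smallest p belonged to a mitochondrial tRNA, ENSRNOT00000045499.3, lower by -2.62 (SE 0.381, from 95.1 ± 20.1 to 15.1 ± 5.50 CPM, edgeR adjusted p = 0.0773). The misc_RNA ENSRNOT00000090994.1 was higher by 1.27 (SE 0.213, adjusted p = 0.0773), with a near-identical copy beside it, miR-423-5p was higher by 1.62 (SE 0.298, adjusted p = 0.0773), and a precursor transcript of the Ensembl miRNA class was lower by -1.30 (adjusted p = 0.0773). Among piRNAs, small RNAs best known from the germ line, piR-84460 (1.61) and piR-72418 (2.00) were higher and piR-64122 was lower (-1.57), each at adjusted p = 0.133. The mitochondrial rRNA ENSRNOT00000069133.1 was lower by -3.48 (SE 0.814, adjusted p = 0.133) and miR-223-3p by -1.13 (SE 0.295, adjusted p = 0.133). Of the abundant features, ENSRNOT00000090410.1 (-0.00), piR-63429 (0.17), miR-148a-3p (-0.83), piR-63455 (-0.91) and piR-63454 (-0.95) did not pass, with edgeR adjusted p from 0.192 to 0.996. Without scaling, which moved the median from 0.12 to 0.32, edgeR called 4 (3 higher, 1 lower). Without oil library 2 it called 26 (8 higher, 18 lower).

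The fixed lists gave 4 calls of 13 for CBZ by camera. Red blood cell miRNAs were lower (8 of 9 members, median -0.44, camera adjusted p = 0.0224; adjusted p = 0.417 with an estimated correlation). Of its abundant members miR-486 (-0.41, edgeR adjusted p = 0.313) and miR-25-3p (-0.20, adjusted p = 0.664) were lower and miR-92a-3p higher (0.50, adjusted p = 0.289). The miR-17-92 and related clusters, tied to cell proliferation, were lower in 7 of 8 members (median -0.38, camera adjusted p = 0.0481; adjusted p = 0.417 with an estimated correlation), and they share 4 tested members with the red blood cell list, miR-25-3p, miR-92a-3p, miR-93-5p and miR-363-3p. The tRNA fragments were higher in 53 of 69 genes (median 0.59, camera adjusted p = 3.00e-04; adjusted p = 0.731 with an estimated correlation), with a LysCTT gene (1.03) and a GluCTC gene (0.72) higher in every CBZ than in every oil library, each at edgeR adjusted p = 0.137. Their most abundant genes, of GlyGCC, were at 0.15, and at -0.01 with DESeq2 size factors. Many of the tRNA genes are near-identical copies here too, so the count of genes and the camera p of that list count the same reads repeatedly. The red blood cell and miR-17-92 calls were each lost without any 1 of oil libraries 1, 2 and 3 and CBZ libraries 1 and 2 (adjusted p from 0.0539 to 0.147), and with near-identical copies counted once. The rRNA fragments were lower in 18 of 26 (median -2.80, camera adjusted p = 3.46e-04; adjusted p = 0.731 with an estimated correlation). Oil library 2 held 26.7% rRNA, and without it the median was -0.76 (camera adjusted p = 5.92e-09), while without oil library 1 the call was lost (adjusted p = 0.155). Adjusted over the list alone 11 rRNA fragments fell with edgeR and 0 members of the other 3 lists passed. Fry called 2 lists, red blood cell miRNAs (adjusted p = 0.0343) and the miR-17-92 clusters (0.0378). Among miRNAs alone camera called those (0.0234 and 0.0438) and vascular and fibroblast miRNAs, higher (0.0438), and 0 lists with an estimated correlation. Of the 13 lists 1 was called without oil library 1 and 2 without oil library 2.

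Of the lists without a call for CBZ, the vascular and fibroblast miRNAs were higher in 6 of 6 members (median 0.56, camera adjusted p = 0.0572), among them miR-143-3p (0.86), miR-26a-5p (0.51) and miR-99a-5p (0.56). Liver miRNAs did not pass (camera adjusted p = 0.804), and miR-122-5p was higher by 1.60 (edgeR adjusted p = 0.137). Among miRNAs alone miR-122-5p was higher by 1.53 (edgeR adjusted p = 0.138), with overlapping libraries. There the DESeq2 Wald test called it (adjusted p = 0.00655), as did edgeR without scaling, without a filter and with the replicate block. It was not called there with DESeq2 size factors, upper quartile scaling, limma or all 12 libraries in 1 fit. For platelet miRNAs (camera adjusted p = 0.994) the median was -0.03 and the mean 0.06, and for white blood cell miRNAs (0.994) they were -0.02 and 0.03, with both tests pointing up. In the liver list the median was -0.30, the mean 0.04 and the test pointed down. Kidney and epithelial miRNAs (0.510), the let-7 family (0.850), the miR-30 family (0.861), p53-responsive miRNAs (0.510) and piRNAs (0.510) gave no call. Adjusted over the list alone 1 platelet miRNA rose (miR-126a-3p) and 1 fell (miR-223-3p), and 2 piRNAs rose and 1 fell. In both comparisons the brain list had 1 tested member, miR-128-3p, which rose adjusted over the list alone, and the pancreas list 2, miR-7a-5p (0.17 with EGME, -0.61 with CBZ) and miR-375-3p (0.59 and 0.83). The muscle list had 2 for CBZ, miR-378a-3p (0.43) and miR-1-3p (0.32), and snoRNA and snRNA fragments had 0 tested there. The lists of messenger RNAs (germ cell, Sertoli cell, Leydig cell, liver, red cell, platelet, ribosomal protein and mitochondrial transcripts) and of Y RNA had no feature named in either table. The Ensembl transcripts, all misc_RNA among them, carry only an ID and a class, so this does not show that these RNAs were absent.

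In shares of counts, tRNA fragments made up 30.6% ± 7.80 of the oil libraries and 39.4% ± 3.58 of the CBZ libraries, with every CBZ library above every oil library (SD, n = 3; exact permutation p = 0.1). The difference was 8.80 percentage points, and 4.32 without oil library 2. With near-identical gene copies counted once the tRNA share was 6.56% with oil and 9.04% with CBZ (exact permutation p = 0.1). Mitochondrial rRNA was at 0.180% ± 0.211 in the oil and 0.0127% ± 0.00438 in the CBZ libraries, and mitochondrial tRNA at 0.0349% ± 0.0180 and 0.00539% ± 0.00307, lower in every CBZ library (exact permutation p = 0.1 each). The difference in mitochondrial rRNA was -0.167 percentage points, and -0.0465 without oil library 2. The shares of misc_RNA (19.3% and 22.5%, exact p = 0.5), miRNA (21.1% and 20.3%, exact p = 0.9) and piRNA (17.2% and 14.4%, exact p = 0.9) did not differ beyond the spread. The rRNA share was 11.1% ± 13.6 with oil and 3.00% ± 0.238 with CBZ (exact p = 0.4), a difference of -8.13 percentage points that was -0.350 without oil library 2. The share was 26.7% (interval 26.5 to 26.9) in oil library 2, the library of lowest depth, against 5.03% (4.96 to 5.10) and 1.67% (1.64 to 1.71) in the others. Of 7 classes of cellular RNA (rRNA, mitochondrial rRNA and tRNA, snoRNA, snRNA, scaRNA and lincRNA), all 7 had their highest share in oil library 2. Over 12 classes the lowest Benjamini-Hochberg adjusted value was 0.3.

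MicroRNAs enriched in testis and germ cells were scarce in every library. The list had 20 named members in the EGME table and 10 in the CBZ table, and 0 reached the tested level. Together they had 16 to 29 counts per library in the water and EGME groups, or 24.1 ± 4.88 CPM with water and 27.8 ± 9.32 with EGME (SD, n = 3; exact permutation p = 0.6). In the oil and CBZ groups they had 2 to 12 counts, or 12.1 ± 8.52 CPM with oil and 17.2 ± 8.90 with CBZ (exact permutation p = 0.5). The highest totals were those of miR-34c-5p, abundant in spermatocytes and spermatids, with 35 counts in the EGME table, and of miR-184 with 15 in the CBZ table.

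Set against each other, the toxicants shared some called miRNAs, in numbers that rested on the setting. Of 113 miRNAs tested in both comparisons, miR-10a-5p, miR-128-3p, miR-320-3p and miR-423-5p rose with both, 4 against 0.637 for independent lists (one-sided exact hypergeometric p = 0.00118), and miR-93-5p fell with both (1 against 0.142, exact p = 0.136). These hypergeometric p-values treat miRNAs as independent draws, though all were measured and scaled in the same libraries. They do not measure the spread between libraries. Shared rises were 2 without scaling, without a filter, with all 12 libraries in 1 fit and with the edgeR exact test. They were 1 with upper quartile scaling (miR-423-5p) and 0 with limma on the authors' normalized values. Without EGME library 1 there was 1 (miR-10a-5p), without oil library 1 there were 2, and without CBZ library 1 or 2 there were 0. The shared fall was lost without water library 2, EGME library 1 or 3, or CBZ library 1 or 2, and without oil library 2 there were 2 (with miR-140-3p). None of the called miRNAs went opposite ways past the threshold (0 shared in either opposite direction). Across the 113 miRNAs, which are not independent replicates, the log2 fold changes had a Pearson r of 0.481 (Spearman rho 0.436), with 37 higher in both, 40 lower in both and 36 opposite. Across all 231 features tested in both r was -0.149 (rho -0.197), and across 60 tRNA genes -0.516 (rho -0.669), where 52 were opposite. The last value was -0.21 without water library 3 and -0.24 without EGME library 2. Many of these tRNA genes are near-identical copies that carry nearly the same reads, so the correlation and the count of opposite genes rest on fewer separate signals. Over all classes r was 0.0472 with copies counted once. The comparisons share no control library.

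**Figure D2:**
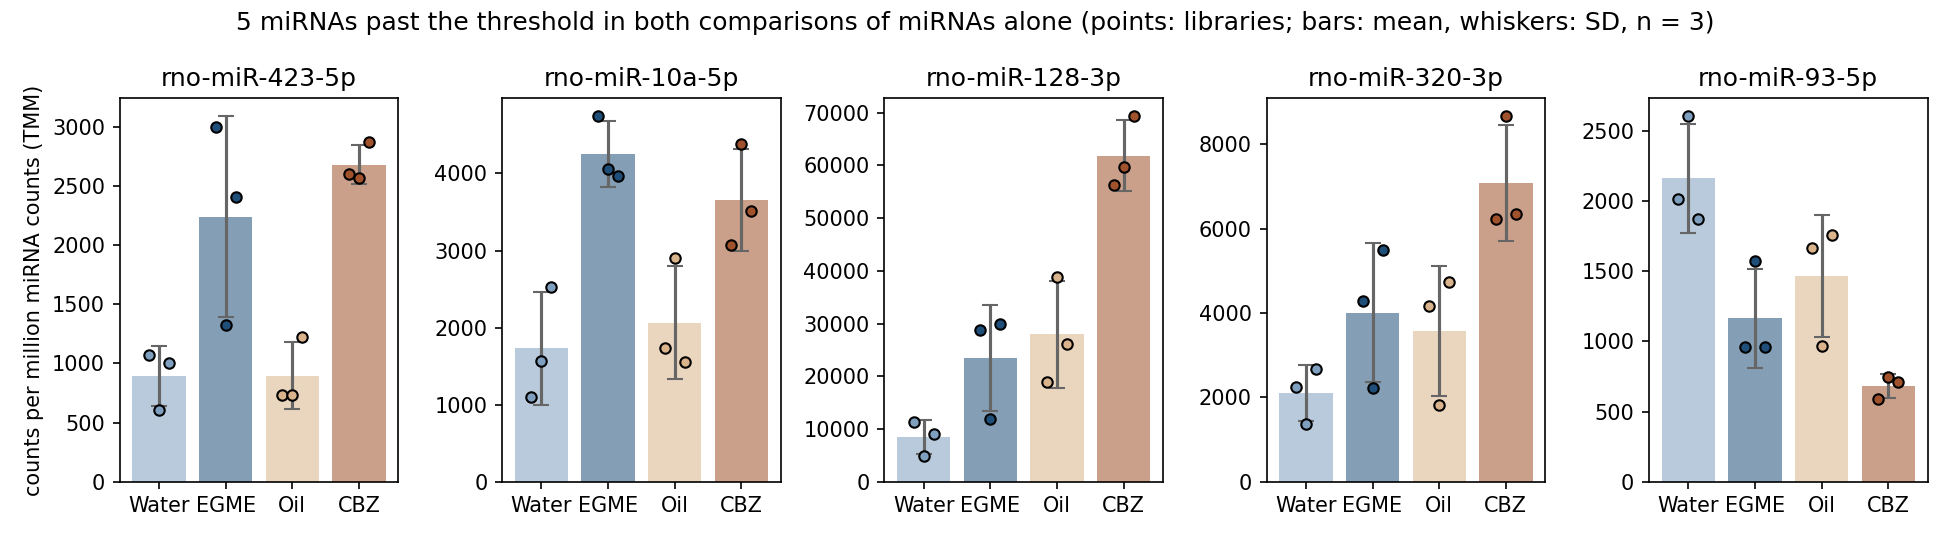
Levels of miR-423-5p, miR-10a-5p, miR-128-3p, miR-320-3p and miR-93-5p (vertical axes, TMM-scaled CPM of the miRNA counts, starting at 0) in the water, EGME, oil and CBZ groups. Points are libraries, bars are means and whiskers are SD (n = 3); miR-423-5p averaged 896 with water and 2239 with EGME, and 898 with oil and 2679 with CBZ.

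The contrast of the toxicants' effects was called for 0 of 327 features by edgeR, with 81 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0505, while the DESeq2 Wald test called 32. The 6 smallest p were those of an rRNA feature and 5 LysCTT tRNA genes. The rRNA feature differed by 4.58 (SE 1.12, adjusted p = 0.0505; 1.45 with EGME and -3.13 with CBZ). The tRNA genes differed by -2.18 to -2.04 (adjusted p = 0.0505), the last of them by -1.07 with EGME and 1.02 with CBZ, and they carry nearly the same reads. Among miRNAs alone 0 of 146 passed with edgeR, with 16 at an unadjusted p under 0.05 and a lowest adjusted p of 0.271. The miRNAs called for 1 toxicant are therefore not shown by this fit to differ between them. For miR-215 the contrast was -1.50 (SE 0.528, edgeR adjusted p = 0.271) and for miR-223-3p it was 1.08 (adjusted p = 0.271). In fits over all classes 2 miRNAs were called by the DESeq2 Wald test and 4 by edgeR without oil library 1. Over all classes edgeR called 0 with near-identical copies counted once. It called 25 with DESeq2 size factors (13 tRNA and 10 rRNA features among them) and 28 without scaling (22 tRNA and 5 rRNA features among them). It called 20 without EGME library 2, 57 without oil library 1, 37 without oil library 2, 42 without oil library 3 and 22 without CBZ library 1.

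**Figure D3:**
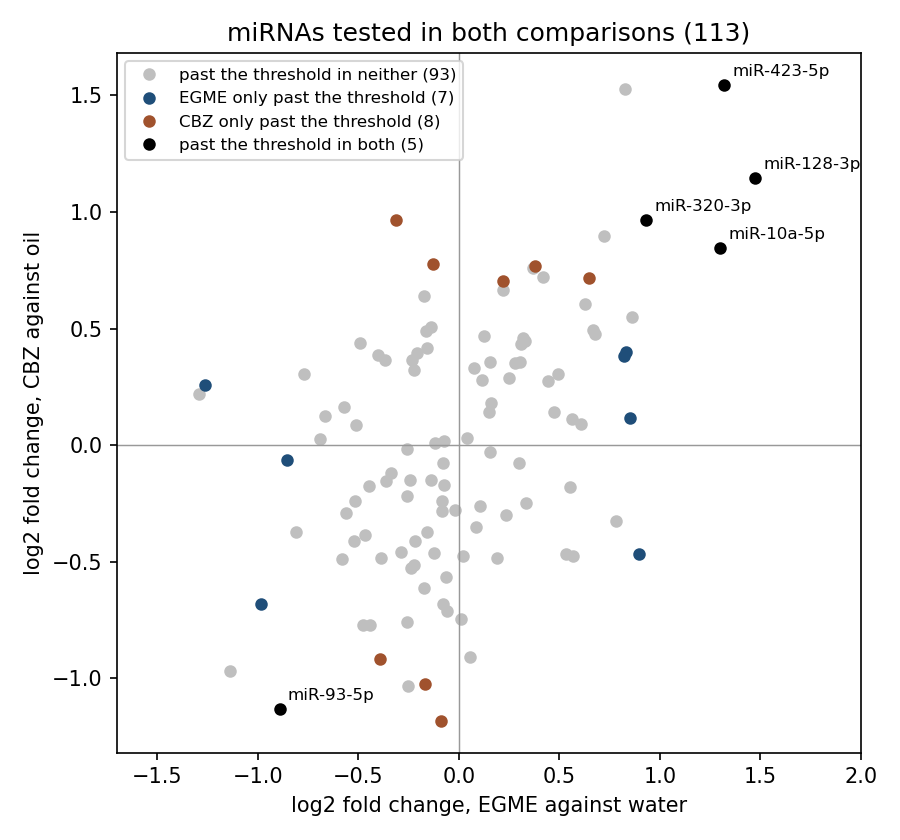
Log2 fold changes of 113 miRNAs with EGME against water (horizontal axis) and CBZ against oil (vertical axis), from the fits of miRNAs alone, 1 point per miRNA. Black points (5) passed the threshold in both comparisons, coloured points in EGME (7) or CBZ (8) alone and grey points (93) in neither; r was 0.481.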

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

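The tests in this part, on gene copies, on oil library 2 and on the correlation over tRNA genes with its splits, were chosen after the result was seen. The tRNA share of counts was lower with EGME and higher with CBZ, and the log2 ratios of the toxicants differed by -1.39 (exact p = 0.025 over 400 arrangements, 0.3 after adjustment over 12 classes, so it failed the correction). With near-identical copies counted once the difference was -1.81 (exact p = 0.02), so the extra weight of such copies does not account for it. Merging them scales treated and vehicle libraries nearly alike, and copies that share only part of their reads were not merged. Reads shared between gene copies can therefore not be judged further by this test. Without oil library 2, with 26.7% rRNA, the difference was -1.16. This value cannot decide on that library, since the EGME part of -0.99 holds no oil library. The CBZ part, the only one it can move, was 0.16 without it against 0.40 with it. Oil library 2 therefore stays open as a cause of much of the CBZ rise. Chance is not excluded: over 60 tRNA genes 6 of 100 splits gave a correlation between the comparisons as large as the real 0.516 in size, and the highest other was 0.653. An effect of the toxicants on tRNA fragments stays open beside it, and may differ between EGME and CBZ, but was not tested apart from these values.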

How the results depend on the processing

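Counts over all classes rested on the scaling, the tool and single libraries. In some settings they stayed at 0. For EGME these were DESeq2 size factors, all 12 samples in 1 fit, copies counted once and the quasi-likelihood test on the features of the authors' table. For CBZ they were DESeq2 size factors, upper quartile scaling, the strict filter, limma, the replicate block and the quasi-likelihood test on the features of the authors' table. For the contrast they were copies counted once, miRNAs only and the replicate block. For EGME, 0 with edgeR (59 at an unadjusted p under 0.05), the count was 34 with upper quartile scaling, 27 with library size only, 12 with no filter, 14 with the strict filter, 20 with the DESeq2 Wald test, 11 with limma on the authors' normalized values, 14 with the edgeR exact test on the features of the authors' table and 13 with miRNAs only, and 0 to 60 when 1 library was left out (60 without EGME library 2, 1 without water library 3). For CBZ, 0 with edgeR (64 at an unadjusted p under 0.05), it was 4 with library size only, 21 with no filter, 24 with the DESeq2 Wald test, 17 with all 12 samples in 1 fit, 2 with the exact test, 13 with miRNAs only and 1 with copies counted once, and 0 to 26 when 1 library was left out (26 without oil library 2). The contrast of the toxicants, 0 with edgeR (81 at an unadjusted p under 0.05), gave 25 with DESeq2 size factors, 28 with library size only, 39 with no filter and 32 with the DESeq2 Wald test. It gave 0 to 57 when 1 library was left out (20 without EGME library 2, 57, 37 and 42 without oil libraries 1, 2 and 3, 22 without CBZ library 1). Among miRNAs alone the 13 calls for EGME became 6 with DESeq2 size factors, 8 with library size only, 1 with limma, 3 with all 12 samples in 1 fit and 7 with the exact test, and 3 to 19 when 1 library was left out (3 without EGME library 1, 6 without EGME library 3, 7 without water library 2). The 13 for CBZ became 3 with library size only, 1 with limma, 6 with all 12 samples in 1 fit and 7 with the exact test, and 0 to 19 when 1 library was left out (0 without CBZ libraries 1 and 2, with 23 and 18 at an unadjusted p under 0.05, and 7 without CBZ library 3). The 13 kept their sign in both comparisons wherever they were tested. The cause of these shifts was not tested.

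Deviations of same-numbered libraries had r of 0.462, 0.430 and -0.128 for EGME and -0.225, -0.044 and 0.313 for CBZ. Not every library correlated best with its own number. That the numbers are not taken as pairs in the main fit was fixed before the data were examined. For EGME the highest r between libraries of unlike number was 0.209, so a link between same-numbered libraries is not excluded there. With the replicate number as a block the counts over all classes were 33 for EGME (10 higher, 23 lower) and 0 for CBZ (64 at an unadjusted p under 0.05 and 24 by DESeq2 in the fits without it), those among miRNAs alone 17 and 13, the lists 5 and 2, and the contrast 0.

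The EGME lists, 5 with camera, were 0 with an estimated correlation, 0 with fry, 0 among miRNAs only and 3 to 5 when 1 library was left out (3 without water library 3 and without EGME library 3). The CBZ lists, 4 with camera, were 0 with an estimated correlation, 2 with fry and 1 to 6 when 1 library was left out (1 without oil library 1, 2 without oil library 2). In lists without a call the direction of the test turned in 29 cases, in 12 of which the median turned as well and in 17 of which it kept its sign. The values below are the medians in these settings; ranges cover every library left out, also those that turned nothing. For EGME the liver list was at -0.21 with fry, -0.44 among miRNAs only, -0.33 with copies counted once and -0.24 to 0.10 when 1 library was left out. The red blood cell list was at -0.37 among miRNAs only, -0.25 with copies counted once and -0.14 to 0.031 when 1 library was left out, and the white blood cell list at -0.56 to 0.035. Among miRNAs only the vascular list was at -0.13, the miR-30 family at -0.076 and the miR-17-92 clusters at -0.022. The piRNAs were at 0.27 with fry, 0.20 with copies counted once and -0.22 to 0.40 when 1 library was left out. For CBZ the white blood cell list was at -0.062 among miRNAs only, and the miR-30 family at -0.061 with fry and 0.14 with library size only. When 1 library was left out the CBZ medians ran from -0.49 to 0.13 for liver, 0.038 to 0.28 for platelet, -0.027 to 0.35 for white blood cell, -0.0030 to 0.46 for let-7 and -0.072 to 0.092 for miR-30.

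These single small RNAs, none past the threshold, turned their direction. For EGME, let-7i-5p was at -0.083, miR-21-5p at -0.082 and let-7f-5p at -0.12 among miRNAs only, and let-7f-5p at -0.0060 with copies counted once. The value of let-7g-5p was 0.00824 with DESeq2 size factors, 0.00824 with the DESeq2 Wald test, 0.23 with upper quartile scaling and 0.040 on the features of the authors' table. When 1 library was left out the range was -0.32 to 0.21 for let-7g-5p, -0.10 to 0.44 for miR-21-5p, -0.00096 to 1.12 for miR-203a-3p and -0.10 to 0.59 for the most abundant rRNA feature. For CBZ the most abundant misc_RNA was at 0.22 with library size only, 0.011 with the strict filter, 0.10 with the replicate block and -0.29 to 0.39 when 1 library was left out. The value of piR-63429 was -0.16 on the features of the authors' table and -0.23 to 1.29 when 1 library was left out. The GlyGCC gene was at -0.0059 with DESeq2 size factors, -0.0060 with the DESeq2 Wald test, -0.21 on the features of the authors' table and -0.10 to 0.30 when 1 library was left out.

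The 4 miRNAs that rose with both toxicants became 1 with upper quartile scaling, 2 with library size only, 2 with no filter, 2 with all 12 samples in 1 fit, 2 with the exact test and 0 with limma, and 0 to 6 when 1 library was left out (1 without EGME library 1, 2 without oil library 1, 0 without CBZ libraries 1 and 2). The 1 that fell with both became 0 with DESeq2 size factors, library size only, limma and all 12 samples in 1 fit, 2 with upper quartile scaling, no filter and the DESeq2 Wald test, and 0 to 2 when 1 library was left out (0 without water library 2, EGME libraries 1 and 3 and CBZ libraries 1 and 2, and 2 without oil library 2). These overlaps in other settings were counted after the data were seen.

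The correlation of the fold changes over all classes, -0.149, was 0.481 over miRNAs only, -0.516 over tRNAs only and 0.0472 with copies counted once. Differences in share, in percentage points, turned with copies counted once for EGME in miRNA (-2.57), piRNA (-2.50) and rRNA (-0.0471) and for CBZ in miRNA (2.00). When 1 library was left out they ran from -0.956 to 0.769 for piRNA and -0.0761 to 0.178 for rRNA with EGME, and from -3.95 to 1.91 for miRNA, -5.59 to 2.40 for piRNA and -0.213 to 7.33 for misc_RNA with CBZ. In the other settings 217 values of counts, shares and correlations stayed close (counts within 1.5 times), and 1173 values of single small RNAs or lists kept their direction and side of the threshold. A further 223 kept their direction but were no longer past the threshold, and 154 kept it and passed only there. The testis miRNAs, with 2 to 29 counts per library, did not reach the tested level in the EGME or CBZ fit.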

Other observations

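The splits for the calls, the lists and the correlation over all classes and the test of depth were planned. The correlation over miRNAs alone with its splits and all other tests in this part were chosen after the result was seen. By share of counts, fragments of mitochondrial RNA, rare in every library (31 to 829 counts of mitochondrial rRNA and 9 to 123 of mitochondrial tRNA), were lower with both toxicants. Averaged over the comparisons, the log2 ratio of the share was -2.33 for mitochondrial rRNA and -1.85 for mitochondrial tRNA, lower in 6 of 6 treated libraries than in each vehicle library of their comparison. For each the exact p was 0.005, the smallest that 400 arrangements can give, and 0.03 after adjustment over 12 classes. For mitochondrial tRNA with EGME the margin was thin, with 63 counts in water library 3 and 52 in EGME library 3, at similar totals. Of the 2 mitochondrial tRNA features tested for EGME, 1 was higher and 1 lower (median log2 difference -0.32), with 0 at an unadjusted edgeR p under 0.05. Hairpin transcripts of the Ensembl miRNA class averaged -0.37 (exact p = 0.01, adjusted 0.04), but with CBZ the libraries overlapped (0.297% ± 0.0876 with oil, highest in oil library 2, and 0.242% ± 0.00186 with CBZ; exact p = 0.2), and with copies counted once the CBZ log2 ratio was -0.12 (exact p = 0.9).

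A lower amount of RNA from whole cells in the treated sera would lower other cellular RNA too. The snoRNA share was at -0.46 with EGME (exact p = 0.2) and -0.96 with CBZ (exact p = 0.1). Averaged over the comparisons it was at -0.71 (exact p = 0.02, 0.06 after adjustment over 12 classes). The mitochondrial share was lower also relative to the mean of rRNA, snRNA, snoRNA and lincRNA, by -1.75 on average (exact p = 0.005). With scaRNA added it was lower by -1.72 (-1.01 with EGME, -2.43 with CBZ, exact p = 0.005). This argues against a loss that lowers these classes alike as the whole cause over both comparisons. A loss of cell RNA that lowers the classes unequally cannot be judged from these ratios and stays open. For EGME alone a loss of all classes alike also stays open. The mitochondrial share was lower in every EGME library over rRNA (-1.49), snRNA (-1.12), snoRNA (-0.87) and lincRNA (-1.24, exact p = 0.1 each, the smallest possible). It was not so over scaRNA (-0.33, exact p = 0.5), which was itself at -0.99. Oil library 2, highest in mitochondrial rRNA, is not the whole cause either, as without it the CBZ log2 ratio was -2.18 for mitochondrial rRNA and -2.38 for mitochondrial tRNA. A change in the release or clearance of mitochondrial RNA after either toxicant may be considered as a hypothesis, but handling that differed between treated and vehicle sera stays open, since the labels give no order of preparation.

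The miRNA fold changes of the toxicants correlated (r = 0.481 over 113 miRNAs, 0.346 to 0.557 when 1 library was left out), and 2 of 100 splits gave a value as large, the real one included (highest other 0.529). That share of 0.02 is under 0.05 alone but 0.06 after adjustment over the 3 correlations tested, so chance is not excluded once these are counted. Without the red blood cell list r was 0.469 over 104 miRNAs, which argues against the miRNAs of that list as the whole cause. Red cell RNA would move its abundant miRNAs together, and here the members were divided. With EGME miR-486 and miR-451-5p differed by 0.926 (SE 0.332, 0.53 against -0.39), but miR-25-3p, also abundant, moved with miR-486 (0.33). With CBZ miR-486 was at -0.47, miR-451-5p at -0.92 and miR-25-3p at -0.25. Depth is also argued against, since with every library thinned to 196460 counts r was 0.440 over 83 miRNAs, with 11 calls for EGME and 13 for CBZ. A response shared by the toxicants, in which miR-10a-5p, miR-128-3p, miR-320-3p and miR-423-5p rise, is one hypothesis that may be followed up, though 0 shared rises were left without CBZ library 1 or 2, and a general effect of illness or reduced feeding was not tested.

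The 6 libraries of a comparison can be split in 10 ways, the real one included, too few for a share under 0.05. For miRNAs alone 1 of 10 splits called as many with EGME (13, highest other 1) and 1 of 10 with CBZ (13, highest other 2). For the lists it was 2 of 10 with EGME (5, highest other 5) and 1 of 10 with CBZ (4, highest other 3). Over all classes, where the real edgeR count was 0 (59 and 64 at an unadjusted p under 0.05, 20 and 24 calls by DESeq2), 10 of 10 did so with EGME (highest other 1) and 10 of 10 with CBZ (highest other 0), as any split must. For the contrast of the toxicants, with 0 calls by edgeR (81 at an unadjusted p under 0.05, 32 calls by DESeq2), all 100 of 100 drawn splits gave as many, which a real count of 0 brings about by itself, and the highest other was 20. Chance is not excluded for the correlation over all classes, where 46 of 100 splits gave one as large in size as the real 0.149 (highest other 0.433).

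Of 231 features tested in both comparisons, 4 had every EGME library on one side of water and every CBZ library on the opposite side of oil, against 1.16 by chance (0.5%). Of these, 2 were tRNA genes. Features are not independent, and near-identical gene copies separate together, so whether this count exceeds chance cannot be judged from these numbers.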
